A study of Mus musculus with 18 samples.

How the data were processed

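The series holds MARS-seq libraries of sorted myeloid cells from mice of the C57BL/6J strain that carry a green fluorescent protein reporter in the Cx3cr1 gene. MARS-seq sorts single cells into wells of a plate, marks each transcript with a unique molecular identifier (UMI) and sequences the 3' end of polyadenylated RNA. Each of the 18 libraries is an amplification batch of 192 wells, 190 of them with 1 sorted cell and 2 left empty. The libraries were grouped by tissue and developmental stage as the labels give them, into yolk sac at embryonic day 12.5, brain at embryonic day 12.5, brain at embryonic day 18.5 and adult brain.

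The authors deposited a table of UMI counts per gene and well, which were whole numbers and not normalized. Per the submitters' processing notes, reads were handled with bcl2fastq 2.15.0.4 and build mm9. The aligner, the collapsing of UMIs and the gene annotation are not given in the sources used here. The highest count of a gene in a well was 256, which may be a ceiling set by the length of the molecular tag, so that the level of the most abundant transcripts in the deepest wells can be understated. The table has 27297 gene rows, and 2109 of these join several symbols, so that such a row cannot be given to 1 gene. Of all rows, 17618 carried a current symbol of the reference annotation and 1712 an older symbol of a single gene. The annotation was used for names only, and no coordinate is reported because its build differs from mm9.

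Wells were kept as cells when the deposited well annotation gave 1 sorted cell and at least 300 UMIs were counted on genes. This left 3012 of 3420 single-cell wells, with 408 left out, 129 of them adult. The 36 empty wells held a median of 24 UMIs and at most 80. No doublet caller was run, because each well received 1 sorted cell. The UMI counts of the kept cells were summed per library, giving totals from 74562 to 534219. Levels are given as CPM, counts scaled to the library total, as mean ± SD over libraries. A count of 3 over a group was taken as the floor of detection, and a fold change against a group with 0 counts is given as a lower bound from this floor. Where the lower group held 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval. These intervals and floors cover counting error only.

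Changed genes were called with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM factors, the filterByExpr filter and a robust quasi-likelihood F-test in 1 fit of all 18 libraries. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, over 4883 tested genes. Fold changes are on the log2 scale with their standard errors. Gene lists fixed from textbook knowledge were tested with camera at an inter-gene correlation of 0.01, adjusted over the 23 lists that had a tested member, and members were also counted after adjustment over the list alone. The mitochondrially encoded transcripts had no tested member and give no result. The genes named for size were, per comparison, the 6 largest rises and 6 largest falls among called genes with a single symbol, a mean of at least 100 CPM in the higher group and no overlap between libraries, leaving out ribosomal, mitochondrial, hemoglobin and numbered genes. For each list described in full, up to 3 called members with the largest change and 1 member that did not pass were named, and the genes of the sort gate in every comparison. These rules, the groups, tests and lists were set before the data were examined, unless stated otherwise. Members named only to identify a count of 5 or fewer were chosen after their values were seen. Some genes that these rules name are not reported here.

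Each pair of libraries of a group was compared by a chi-square test over genes. No pair agreed within sampling noise, with chi-square per degree of freedom from 1.44 to 2.08 within a plate and from 1.73 to 4.60 between plates, so no libraries were merged and each entered the fits as 1 replicate. Such spread may be technical and does not show that libraries are independent. Pairs within a plate were closer than pairs between plates in E12.5 brain (1.44 to 1.65 against 3.94 to 4.47) and in yolk sac (1.76 to 1.97 against 3.44 to 4.60), while the ranges overlapped at E18.5 (1.61 to 2.08 against 1.73 to 3.02) and in adult brain (1.98 to 2.02 against 1.91 to 2.16). The well annotation gives 9 plates with 2 libraries each, 3 sequencing batches, and 1 subject number for all libraries of an age.

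For the share of cells with cell-cycle transcripts, each cell was thinned to 300 UMIs and counted when it held at least 2 UMIs of 40 gene rows of the S phase and G2/M lists. Shares were compared by two-sided exact permutation tests over libraries with Benjamini-Hochberg adjustment. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, 30 principal components, 15 neighbours and a resolution of 1. The rule that names clusters from the marker lists was rewritten once the clusters had been seen. Of the 9 clusters, 6 were named macrophage or microglia-like, and 3 stayed unnamed because a marker of another class led them, Cd74 in 1 and Nes in 2. Cell classes were therefore not compared between groups. In their place the share of the cluster with the lowest C1q and Csf1r level was compared by the same permutation test. This choice was made after the clusters were seen. For the assignment of cells, each library was held out, group profiles were built from the other libraries with 1 UMI per 100000 added, and each cell, thinned to 300 UMIs, was given to the most likely profile.

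The edgeR step was tested on simulated counts with 200 changed genes. Simulated libraries were drawn independently around a common profile, without plate or batch effects. The false calls below therefore do not measure the error rate in the real libraries. For yolk sac against brain at E12.5 it ran on 4579 genes, recovered 39% of genes changed 2-fold and 90% of those changed 4-fold, and made 3 false calls among 132. For E18.5 against E12.5 brain it ran on 4647 genes, recovered 53% and 91%, and made 2 false calls among 146. For adult against E18.5 brain, on 4581 genes, it recovered 29% and 86% with 3 false calls among 118. For adult against E12.5 brain, on 4566 genes, it recovered 30% and 75% with 8 false calls among 113. The assignment step gave all 200 simulated cells of each group to their own profile.

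Alternatives were other scaling (RLE), DESeq2 1.42.0, no filter on low counts, minimums of 150 and 600 UMIs per cell, libraries thinned to 1 total, counts summed per plate, sequencing batch as a covariate, only the compared groups in the fit, a minimum log2 fold change of 1, an estimated inter-gene correlation, and each library left out in turn. Counts and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.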

Results

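Transcriptomes of single myeloid cells were measured by MARS-seq in 18 libraries from yolk sac and brain of reporter mice, to follow how microglia, the resident macrophages of the brain, change from their embryonic origin to the adult. Yolk sac cells at embryonic day 12.5 (E12.5) gave 4 libraries and 671 cells, brain cells at E12.5 4 libraries and 718 cells, brain cells at embryonic day 18.5 (E18.5) 6 libraries and 992 cells, and adult brain cells 4 libraries and 631 cells. The E12.5 cells were sorted as positive for CD45, CD11b and the Cx3cr1 reporter, and the later cells at intermediate CD45 and CD11b, so the gate changed together with age between E12.5 and E18.5. Total UMIs per library ran from 269698 to 309084 in yolk sac, 228467 to 534219 in E12.5 brain, 143876 to 217647 in E18.5 brain and 74562 to 99494 in adult brain. The median UMIs per cell were 1511, 1725, 983 and 521 in the same order. All libraries of an age carried the same subject number in the well annotation, and 2 libraries shared each plate, so p-values measure only the spread between these libraries, which may be technical.

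The first comparison set yolk sac cells against brain cells of the same age and gate, so that tissue was the planned difference. The brain cells held the transcripts of microglial identity at E12.5, which were low in the yolk sac cells. Tmem119, a membrane protein of microglia, was at 749.7 ± 118 CPM in brain and 25.01 ± 8.25 CPM in yolk sac (SD, n = 4 each), a log2 fold change of −4.84 (SE 0.21, edgeR adjusted p = 9.94e-22). The yolk sac cells held Pf4, a chemokine of embryonic macrophages and platelets, at 3002 ± 316 CPM against 98.2 ± 53.6 CPM in brain, a log2 fold change of 4.89 (SE 0.41, edgeR adjusted p = 1.50e-07). Genes of the type I interferon response were also higher in yolk sac. For each gene named for the size of its change, every library of one tissue lay above every library of the other, as the naming rule required.

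All 19 measured homeostatic microglia markers fell in yolk sac relative to brain, over all genes and adjusted over the list alone (camera adjusted p = 1.30e-55). Sall1, a transcription factor of microglial identity, was at 3.35 ± 4.58 CPM in yolk sac and 139 ± 20.5 CPM in brain (log2 fold change −5.07, SE 0.41). Olfml3, a secreted glycoprotein, was at 30.3 ± 18.3 and 1171 ± 292 CPM (log2 fold change −5.18, SE 0.24). Of 11 embryonic, yolk sac and border macrophage markers, 10 rose, and 11 adjusted over the list alone (camera adjusted p = 2.78e-24). Clec10a, a C-type lectin, was at 355 ± 132 CPM in yolk sac and 4.01 ± 4.66 CPM in brain (log2 fold change 6.34, SE 0.46), and F13a1, a clotting factor subunit, at 458 ± 186 and 8.33 ± 10.1 CPM (log2 fold change 5.38, SE 0.76). The row that joins the near-identical lysozyme genes Lyz1 and Lyz2 was at 1051 ± 1044 and 247 ± 233 CPM and did not pass (edgeR adjusted p = 0.115).

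**Figure D1:**
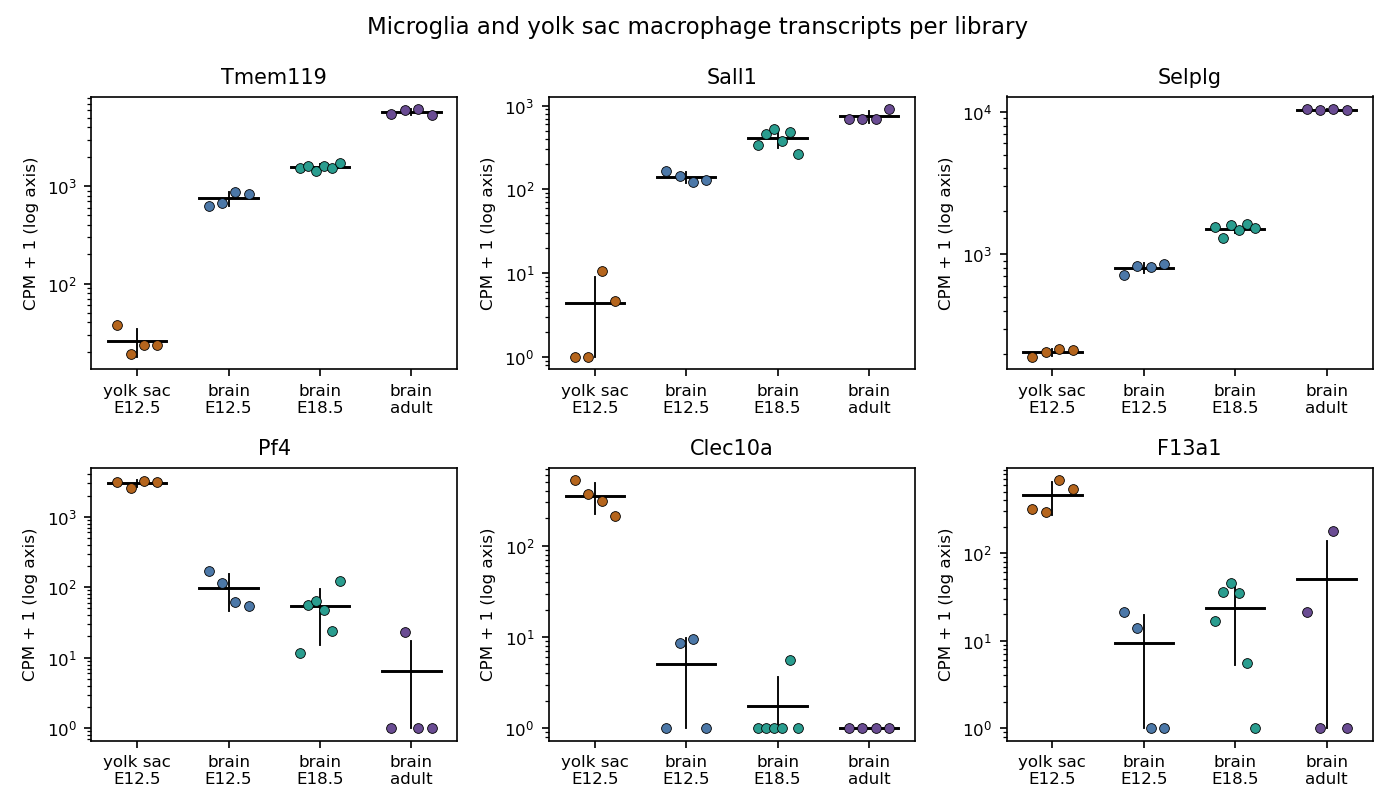
Levels of Tmem119, Sall1, Selplg, Pf4, Clec10a and F13a1 in each library, in CPM plus 1 on a log axis, for yolk sac and brain at E12.5, brain at E18.5 and adult brain; points are libraries, bars the mean and whiskers 1 SD. Tmem119 stood at 25.01 CPM in yolk sac and 749.7 CPM in E12.5 brain, and Pf4 at 3002 and 98.2 CPM.

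All 9 measured interferon response genes rose in yolk sac, also adjusted over the list alone (camera adjusted p = 1.81e-10). Ifitm3, an antiviral membrane protein, was at 759.7 ± 619 CPM in yolk sac and 48.8 ± 57.5 CPM in brain (log2 fold change 3.82, SE 0.81). Irf7, a transcription factor of the interferon response, was at 393 ± 205 and 39.7 ± 18.8 CPM (log2 fold change 3.44, SE 0.56), and Isg15, a ubiquitin-like modifier, at 339.7 ± 199 and 36.5 ± 6.87 CPM (log2 fold change 3.25, SE 0.45). Summed over the list, yolk sac replicates 1 and 2 reached 2549.55 and 2892 CPM and replicates 3 and 4 reached 5662 and 6218 CPM. Brain replicates 3 and 4, which share a sequencing batch with yolk sac replicates 1 and 2, held 716 and 814 CPM.

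Of 11 genes of TGF-beta signalling, a pathway that maintains microglia, 6 fell in yolk sac and 5 did not pass, with 6 also adjusted over the list alone (camera adjusted p = 2.00e-10). Pmepa1, a target and inhibitor of the pathway, was at 25.7 ± 7.24 CPM in yolk sac and 509.7 ± 111 CPM in brain (log2 fold change −4.24, SE 0.23). The type I receptor Tgfbr1 was at 25.5 ± 9.08 and 475 ± 139 CPM (log2 fold change −4.15, SE 0.26) and the inhibitory Smad7 at 7.04 ± 3.93 and 77.95 ± 16.7 CPM (log2 fold change −3.30, SE 0.44). The ligand Tgfb1 was at 523 ± 81.4 and 471 ± 65.8 CPM (edgeR adjusted p = 0.558). Among 10 chemokines and their receptors, Ccl2, the Ccl3 row, Ccl6, Ccl9 and Pf4 rose and Cx3cr1 and Cxcr2 fell, 6 and 2 adjusted over the list alone (camera adjusted p = 0.000677, adjusted p = 0.0599 with an estimated correlation). Ccl2, which attracts monocytes, was at 109 ± 52.0 CPM in yolk sac and 4.01 ± 6.83 CPM in brain (log2 fold change 4.30, SE 0.53). Cxcr2, a receptor of neutrophil chemokines, was 15.8 times higher in brain by summed counts (exact 95% interval 5.18 to 78.9, 3 UMIs in yolk sac).

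Of 4 MHC class II presentation genes, H2-DMa, the H2-DMb row and the protease Ctss fell, 3 also adjusted over the list alone (camera adjusted p = 0.00683). In iron and heme handling, Hmox1, Blvra, Blvrb, Ftl1 and Trf rose and the metal transporter Slc11a1 fell among 9 genes, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0334, adjusted p = 0.0599 with an estimated correlation). That call was lost without brain replicate 1 or yolk sac replicate 1, with camera adjusted p from 0.0117 to 0.0760 over the left-out libraries. Outside the lists, the lipid carrier Pltp was at 190.1 ± 28.0 CPM in yolk sac and 5.67 ± 5.40 CPM in brain (log2 fold change 5.05, SE 0.49) and the endothelin receptor Ednrb at 231 ± 99.6 and 7.56 ± 5.25 CPM (log2 fold change 4.73, SE 0.43). The junction protein F11r was at 11.4 ± 7.62 and 552 ± 38.7 CPM (log2 fold change −5.48, SE 0.28) and the protease inhibitor Serpine2 at 18.1 ± 18.9 and 797 ± 137 CPM (log2 fold change −5.35, SE 0.38). Spsb1 was 161 times higher in brain by summed counts (exact 95% interval 28.7 to 6407, 1 UMI in yolk sac) and Spint1 119 times (32.6 to 986, 2 UMIs). Few markers of other blood cells were tested, and few were called. In yolk sac 1 of 4 granulocyte precursor markers, 1 of 4 erythroid and 1 of 3 monocyte markers rose, and the progenitor markers Cd34 and Sox4 fell. The median log2 fold changes of the first 3 classes were 3.42, 5.03 and 2.06, so the missing calls do not show equal levels. For Prtn3 (104 to 316 against 16.2 to 74.4 CPM) and Mpo (174 to 423 against 56.6 to 68.6 CPM) the libraries of yolk sac and brain did not overlap, and for Ctsg they did. The tested platelet, T cell and B cell markers did not pass. Elane, the neutrophil elastase, was at 202 ± 219 CPM in yolk sac and 8.47 ± 6.42 CPM in brain (log2 fold change 4.81, SE 1.15), and hemoglobin transcripts summed to 2532 ± 2367 and 74.6 ± 72.5 CPM.

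In all, edgeR called 774 of 4883 genes in this comparison, 344 higher and 430 lower in yolk sac. Which direction held more genes depended on the setting, with 403 higher and 367 lower in DESeq2. Plates within a group differed too: in a fit by plate, 2 libraries against 2, edgeR called 297 genes between the yolk sac plates and 497 between the E12.5 brain plates, each pair also parted by sequencing batch. The embryonic and border macrophage markers differed between the yolk sac plates (camera adjusted p = 0.00256, adjusted p = 0.0403 with an estimated correlation) and between the E12.5 brain plates (camera adjusted p = 0.0147, adjusted p = 0.0953 with an estimated correlation). The interferon genes (camera adjusted p = 3.16e-06), the phagocytic genes (0.000145) and the list of long noncoding RNAs, measured by Malat1 alone (1.65e-06), also differed between the yolk sac plates, and stayed called there with an estimated correlation (adjusted p = 0.0191, 0.0403 and 0.01002). For Malat1, a single gene, no correlation between genes can be estimated, so that setting is no added check. Libraries of the groups did not overlap for 19.9% of tested genes, where chance gives 2.86% if libraries are independent and up to 33.3% if those of a plate move together. The other splits of whole plates gave at most 12.9%. With sequencing batch as a covariate 520 genes passed, and Elane (log2 1.82) was lost. With counts summed per plate 493 genes passed, and F13a1 (5.50), Ifitm3 (3.95) and Elane (4.84) were lost; with libraries thinned to 1 total 377 passed and Elane (4.50) was lost, and Ifitm3 was lost in a fit of these groups alone (3.84).

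The second comparison followed brain cells from E12.5 to E18.5. Immediate early genes, which respond within minutes to stimulation and also to tissue dissociation, were far higher at E18.5. Fos, a subunit of the AP-1 transcription factor, was at 1189 ± 181 CPM at E18.5 (SD, n = 6) and 6.39 ± 6.79 CPM at E12.5 (n = 4), a log2 fold change of 7.26 (SE 0.33, edgeR adjusted p = 6.29e-17). Microglial markers and lysosomal genes were also higher, as for Crybb1, a crystallin found in microglia, at 3101 ± 790.3 against 485 ± 162 CPM (log2 fold change 2.68, SE 0.21, edgeR adjusted p = 1.53e-12). DNA replication and respiratory chain genes were lower. Every library of one age lay above every library of the other for each changed gene whose values are given here, apart from the gate genes, but not for Hist1h1a, Hist1h2ae and Myd88, which are named only as members of a list. The naming rule required this separation of genes named for size.

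Of 16 immediate early genes, 14 rose and none fell, also adjusted over the list alone (camera adjusted p = 3.89e-46). Egr1, a zinc finger transcription factor, was at 479.7 ± 110.0 CPM at E18.5 and 7.82 ± 3.89 CPM at E12.5 (log2 fold change 6.04, SE 0.33). Fosb was at 38.2 ± 13.6 CPM at E18.5 and at 0 in all E12.5 brain libraries, at least 18.7-fold higher against a floor of 3 counts over the group. Klf2, which did not pass, was at 116 ± 33.3 and 126 ± 28.2 CPM (edgeR adjusted p = 0.842). Dusp1, a phosphatase of MAP kinases, was at 184 ± 49.5 and 5.57 ± 3.93 CPM (log2 fold change 4.83, SE 0.41), and Zfp36, which destabilises cytokine mRNAs, at 496 ± 133 and 35.3 ± 10.5 CPM (log2 fold change 3.77, SE 0.24). Among 16 macrophage and microglia transcription factors 8 rose, also adjusted over the list alone (camera adjusted p = 3.08e-15), and 5 of these, Fos, Egr1, Jun, Junb and Klf6, are also immediate early genes. Jun was at 921 ± 201 and 62.0 ± 16.9 CPM (log2 fold change 3.89, SE 0.28), while Irf8 was at 612 ± 62.6 and 643 ± 22.3 CPM (edgeR adjusted p = 0.718).

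**Figure D2:**
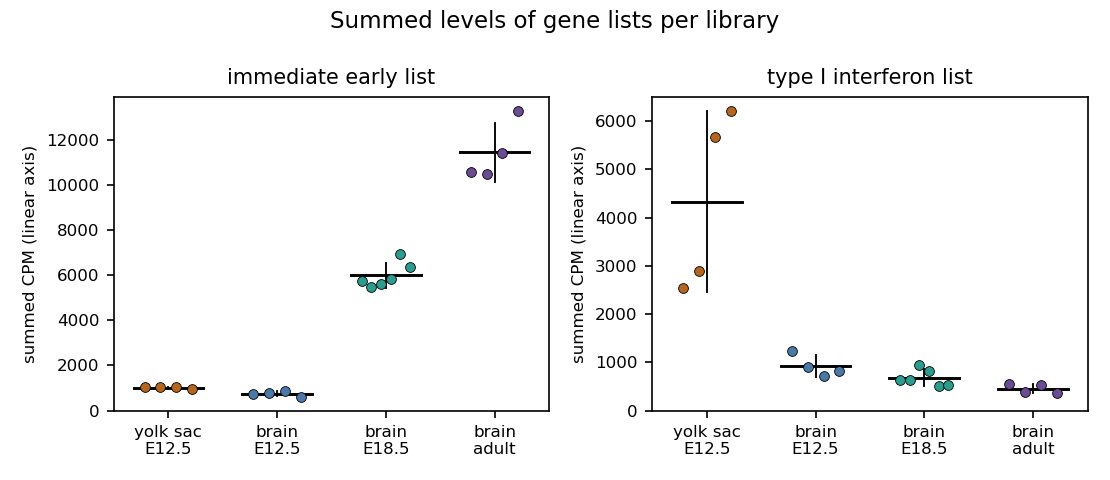
Summed level of the measured immediate early genes and of the measured interferon response genes in each library, in CPM on a linear axis, for the 4 groups; points are libraries, bars the mean and whiskers 1 SD. Immediate early genes summed to 742 ± 108 CPM in E12.5 brain, 1016 ± 46.2 in yolk sac, 5994 ± 544 at E18.5 and 11436 ± 1301 in adult brain.

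Of 19 homeostatic microglia markers 18 rose from E12.5 to E18.5, also adjusted over the list alone (camera adjusted p = 3.88e-20). Ecscr was at 291 ± 85.5 CPM at E18.5 and 55.2 ± 8.97 CPM at E12.5 (log2 fold change 2.40, SE 0.23). Tgfbr1 was at 466 ± 78.3 and 475 ± 139 CPM (edgeR adjusted p = 0.890). In the lysosome and phagocytosis list 20 of 25 rose, also adjusted over the list alone (camera adjusted p = 1.70e-12). The cathepsins Ctsb and Ctsl were at 685 ± 107 and 2773 ± 671 CPM at E18.5, against 144 ± 107 and 682 ± 363 CPM at E12.5 (log2 fold changes 2.16 and 2.01, SE 0.51 and 0.36). Mertk, a receptor for dying cells, was at 107 ± 42.0 and 19.5 ± 13.1 CPM (log2 fold change 2.27, SE 0.42), and Tyrobp at 3324 ± 254 and 3047 ± 492 CPM (edgeR adjusted p = 0.489).

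Of 10 chemokines and receptors 7 rose, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.87e-10). The rows of the inflammatory chemokines Ccl3 and Ccl4 were at 1261 ± 118 and 245 ± 88.5 CPM at E18.5, against 126 ± 69.2 and 16.7 ± 17.3 CPM at E12.5 (log2 fold changes 3.24 and 3.66, SE 0.28 and 0.57). Ccl2 was at 90.9 ± 35.3 and 4.01 ± 6.83 CPM (log2 fold change 3.98, SE 0.53). Pf4 was at 53.3 ± 38.9 and 98.2 ± 53.6 CPM (edgeR adjusted p = 0.125), and without E18.5 replicate 6 it passed at a log2 fold change of −1.41. Of 9 Toll-like receptor signalling genes 6 rose and Myd88 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 0.000151). Of 7 complement genes C1qa, C1qb, C1qc, C5ar1 and Itgam rose, 5 up and 1 down adjusted over the list alone (camera adjusted p = 0.000493). Of 7 histone genes the core histone Hist1h2ae, the linker histones Hist1h1a and Hist1h1c and the row of the linker histone Hist1h1e rose, 4 also adjusted over the list alone (camera adjusted p = 0.00263, adjusted p = 0.137 with an estimated correlation).

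Lower at E18.5 were 13 of 15 nuclear respiratory chain genes, also adjusted over the list alone (camera adjusted p = 1.32e-07). Of 13 DNA replication genes 7 fell and 6 did not pass, with 8 lower adjusted over the list alone (camera adjusted p = 0.00149), while the mitotic list was not called (camera adjusted p = 0.0818). Of 36 ribosomal protein genes 20 fell and Rpl3 rose, with the same counts adjusted over the list alone (camera adjusted p = 8.16e-05, adjusted p = 0.179 with an estimated correlation). Among the largest falls, Igf2bp1, a fetal RNA-binding protein, was at 5.40 ± 7.14 CPM at E18.5 and 135 ± 15.3 CPM at E12.5 (log2 fold change −4.47, SE 0.45). The actin regulators Gsn and Cnn2 were at 23.2 ± 9.45 and 57.6 ± 23.2 CPM, against 229 ± 21.2 and 542 ± 84.5 CPM at E12.5 (log2 fold changes −3.27 and −3.23, SE 0.28 and 0.29). The lectin Lgals1 was at 85.1 ± 26.0 and 636 ± 85.5 CPM (log2 fold change −2.90, SE 0.19), Cyp4f18 at 9.29 ± 10.8 and 115 ± 24.8 CPM (−3.54, SE 0.49) and Klk8 at 27.4 ± 16.5 and 162 ± 39.2 CPM (−2.53, SE 0.35). The immune receptor Lag3 was at 534 ± 101 and 52.9 ± 12.5 CPM (log2 fold change 3.32, SE 0.23).

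In this comparison edgeR called 1195 of 4883 genes, 543 higher and 652 lower at E18.5, and 18.7% of tested genes did not overlap, where chance gives 0.952% for independent libraries and up to 1 in 5 genes if those of a plate move together (other splits of whole plates, at most 4.69%). The direction with more genes turned with RLE scaling, at 596 higher and 567 lower, and with a log2 fold change of at least 1, at 329 and 242. The E12.5 brain plates differed in 497 genes (edgeR, 2 libraries against 2), and in the lists of ribosomal proteins, 21 of 36 higher and 5 lower in the plate of replicates 3 and 4 (camera adjusted p = 3.08e-08), and of lysosome and phagocytosis, 4 of 25 higher and 8 lower (camera adjusted p = 0.0147). With an estimated correlation these lists and the embryonic markers were not called between the plates (camera adjusted p = 0.0953 for all 3). The list measured by Malat1 alone was lower in the plate of replicates 3 and 4 (camera adjusted p = 2.29e-05, adjusted p = 0.0237 in the estimated setting). For 1 gene no correlation between genes can be estimated, so that setting is no added check. No sequencing batch held brain cells of both ages, and with batch as a covariate, estimated from the E12.5 libraries, 332 genes passed; Mertk turned to −1.52, and Dusp1 (4.44), Fosb (5.36), Lag3 (2.33), Ecscr (2.33) and the Ccl4 row (3.30) were lost. With counts summed per plate 660 genes passed and Ctsb (2.24) did not, 621 passed with thinned libraries, and 571 had a log2 fold change of at least 1.

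The third comparison set adult brain cells against E18.5 brain cells, which share gate and sequencing batch. Adult cells held more of the homeostatic markers of microglia. Selplg, a selectin ligand, was at 10363 ± 123 CPM in adult brain (SD, n = 4) and 1513 ± 115 CPM at E18.5 (n = 6), a log2 fold change of 2.81 (SE 0.11, edgeR adjusted p = 2.18e-22), and Tmem119 at 5745 ± 436 and 1569 ± 102 CPM (log2 fold change 1.90, SE 0.13, edgeR adjusted p = 1.31e-14). Apoe, a lipid carrier, was at 1292 ± 713 and 19429 ± 2169 CPM, a log2 fold change of −3.89 (SE 0.31, edgeR adjusted p = 2.03e-07). Ribosomal protein, mitotic and phagocytic genes were lower in adult cells. Every library of one age lay above every library of the other for each changed gene whose values are given here, apart from Spp1. The naming rule required this separation of genes named for size. Of the changed genes named only as members of a list, Ctsh, Mcm2, Mcm4, Pcna, Elane, Tapbp and Pdia3 overlapped.

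Of 19 homeostatic markers 13 rose and Crybb1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.27e-14). Ecscr was at 969 ± 95.9 CPM in adult brain and 291 ± 85.5 CPM at E18.5 (log2 fold change 1.77, SE 0.19), while Fcrls was at 4833 ± 510.1 and 5198 ± 449 CPM (edgeR adjusted p = 0.728). Of 16 transcription factors 9 rose, with 9 up and 1 down adjusted over the list alone (camera adjusted p = 2.78e-06). Mef2a was at 402 ± 91.5 and 128 ± 25.5 CPM (log2 fold change 1.68, SE 0.25) and Jun at 2620.3 ± 593 and 921 ± 201 CPM (1.54, SE 0.22). Fos was at 1258 ± 75.3 and 1189 ± 181 CPM (edgeR adjusted p = 0.750). Of 11 TGF-beta signalling genes 8 rose, also adjusted over the list alone (camera adjusted p = 3.52e-06), and of 16 immediate early genes 7 rose and Ier3 fell, with the same counts adjusted over the list alone (camera adjusted p = 6.05e-06). The MHC class I genes B2m, Tapbp, Psmb9, Pdia3 and the H2-T23 row rose among 13, 5 also adjusted over the list alone (camera adjusted p = 0.00256).

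Of 36 ribosomal protein genes 25 fell and none rose, with 28 lower and 1 higher adjusted over the list alone (camera adjusted p = 5.92e-25). Rpl26 was at 142 ± 65.2 CPM in adult brain and 1741 ± 384 CPM at E18.5 (log2 fold change −3.60, SE 0.30) and the row of Rpl34 and its pseudogene at 69.3 ± 14.3 and 983 ± 296 CPM (−3.78, SE 0.46). Rpl30 was at 16.1 ± 19.2 and 317 ± 134 CPM (log2 fold change −4.17, SE 1.16), and did not pass with cells of at least 600 UMIs (−3.81), with counts per plate (−4.26), or without adult replicate 1 (−4.002) or 3 (−4.01). Rpl32 was at 792 ± 1402 and 1423 ± 492 CPM (edgeR adjusted p = 0.538). Adult replicate 1 held 2895 CPM of it and the other adult libraries 65.9 to 134 CPM, and without that replicate it passed at −3.99.

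In the list of phagocytic microglia genes, which mark developing white matter and disease, 12 of 16 fell, and 13 adjusted over the list alone (camera adjusted p = 1.20e-11). Axl, a receptor for dying cells, was 13.8 times lower in adult brain by summed counts (exact 95% interval 3.69 to 116, 2 UMIs in adult). Lgals1 was at 56.0 ± 28.0 CPM in adult brain and 85.1 ± 26.0 CPM at E18.5 (edgeR adjusted p = 0.213). Spp1, a secreted matrix protein, was 61.2 times lower (10.8 to 2429, 1 UMI in adult), but its call (edgeR log2 fold change −5.73, SE 1.82) was lost without any single adult replicate or E18.5 replicate 2, 3 or 4, at log2 fold changes from −8.39 to −5.36. It was lost as well with no filter on low counts (−5.87), with cells of at least 600 UMIs (−8.35), with counts per plate (−5.89) and in a fit of these groups alone (−5.60).

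Of 16 mitotic genes 13 fell, and 14 adjusted over the list alone (camera adjusted p = 3.64e-10). Tpx2, a spindle factor, was at 80.9 ± 34.0 CPM at E18.5 and 0 in the adult libraries, at least 9.74-fold lower. Birc5, of the chromosomal passenger complex, was 28.5 times lower (exact 95% interval 4.98 to 1140.49, 1 UMI in adult), its partner Cdca8 18.5 times (5.00 to 155, 2 UMIs) and the proliferation marker Mki67 14.3 times (4.77 to 70.1, 3 UMIs). Ube2c was at 77.0 ± 103 and 142 ± 46.2 CPM (edgeR adjusted p = 0.299), and without adult replicate 1 it passed at a log2 fold change of −2.39. The DNA replication genes Mcm2, Mcm4, Mcm5, Pcna and Lig1 fell among 13, and 7 adjusted over the list alone (camera adjusted p = 0.00637).

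Other lists moved as well from E18.5 to adult. In lysosome and phagocytosis 4 of 25 rose, Ctsd, Ctsh and Trem2 among them, and 14 fell, 4 and 15 adjusted over the list alone (camera adjusted p = 0.000202). Of 15 respiratory chain genes 9 fell, and 10 adjusted over the list alone (camera adjusted p = 2.79e-06). Of 8 glycolysis genes 6 fell, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000568). Of 10 chemokines and receptors 6 fell, and 7 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000671). Of 11 embryonic and border macrophage markers Dab2, Ms4a7 and the Stab1 row fell, and 6 adjusted over the list alone (camera adjusted p = 0.00416). Scd2 fell of 2 measured cholesterol and fatty acid synthesis genes, 1 also adjusted over the list alone (camera adjusted p = 0.00640). This last list was not called without adult replicate 2 or 3, with camera adjusted p from 0.00209 to 0.193 over the left-out libraries.

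Among the largest changes outside the lists, Tgm2, a transglutaminase, was at 114 ± 51.5 CPM in adult brain and 0 at E18.5, at least 41.2-fold higher. Thrsp was 191 times higher by summed counts (exact 95% interval 33.1 to 7671, 1 UMI at E18.5). Lrrc3 was at 397 ± 59.7 and 16.6 ± 9.12 CPM (log2 fold change 4.61, SE 0.39), Jam2 at 148 ± 28.8 and 7.97 ± 8.73 CPM (4.21, SE 0.60) and Fam167b at 109 ± 43.3 and 8.50 ± 5.51 CPM (3.65, SE 0.75). Gpx3, a secreted glutathione peroxidase, was 104 times lower in adult brain (exact 95% interval 28.7 to 860.4, 2 UMIs in adult), and Ttyh2 38.4 times (6.75 to 1529.65, 1 UMI). Ctsl was at 292 ± 185 and 2773 ± 671 CPM (log2 fold change −3.21, SE 0.42). The granule protease Prtn3 of granulocyte precursors was at 2770.2 ± 2819.8 CPM in adult brain and 171 ± 119.8 CPM at E18.5 (log2 fold change 4.03, SE 0.70), and 2 of 4 measured granulocyte precursor markers, Prtn3 and Elane, rose.

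**Figure D3:**
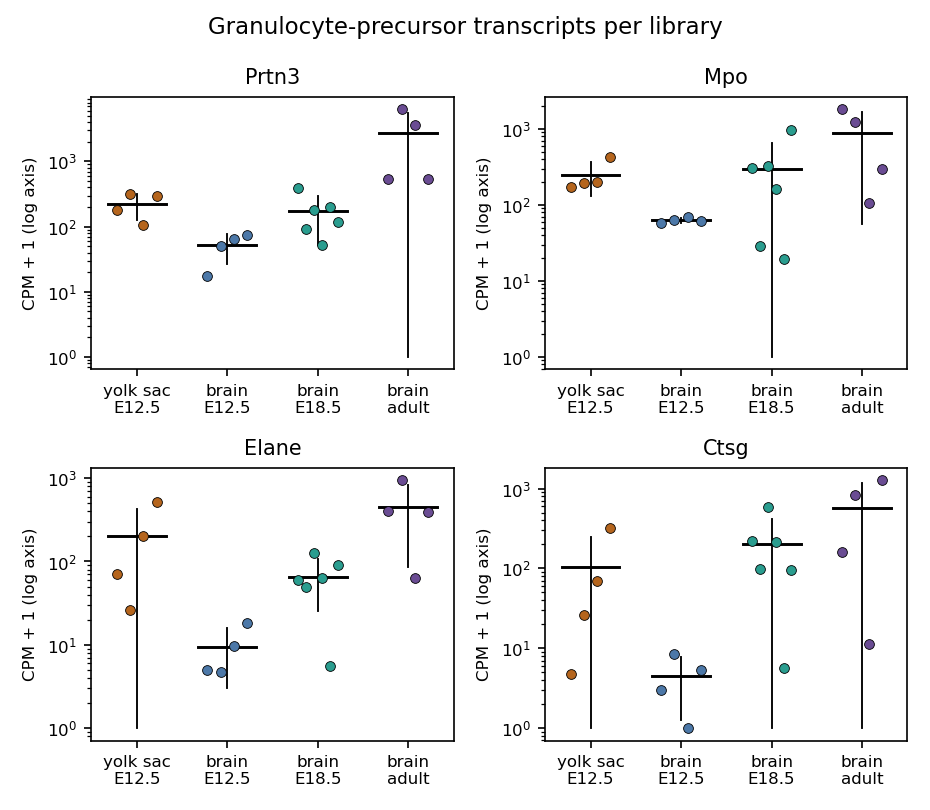
Levels of the granule protein genes Prtn3, Mpo, Elane and Ctsg in each library, in CPM plus 1 on a log axis, for the 4 groups; points are libraries, bars the mean and whiskers 1 SD. Prtn3 averaged 2770.2 CPM in adult brain and 171 CPM at E18.5.

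In this comparison edgeR called 1050 of 4883 genes, 503 higher and 547 lower in adult brain, and 16.8% of tested genes did not overlap, where chance gives 0.952% for independent libraries and up to 1 in 5 genes if those of a plate move together (other splits of whole plates, at most 5.30%). Without the filter on low counts the split was 364 higher and 784 lower. Between plates of 1 age, 2 libraries against 2, edgeR called 12, 28 and 63 genes at E18.5 and 1 in the adult. Ribosomal proteins were lower in the plate of adult replicates 3 and 4 than in the other adult plate (camera adjusted p = 0.000128, adjusted p = 0.455 with an estimated correlation), with no member called. Transcription factors, with no member called either, and Malat1 were higher there (camera adjusted p = 0.0217 and 3.58e-08, adjusted p = 0.455 and 0.00438 with an estimated correlation, which is no added check for the single gene Malat1). The phagocytic genes were lower in the plate of E18.5 replicates 5 and 6 than in the 2 others (camera adjusted p = 0.000529 and 0.000344, adjusted p = 0.178 and 0.112 with an estimated correlation). Against replicates 1 and 2 that plate was also lower in DNA replication and lysosome genes (camera adjusted p = 0.0132 and 0.0252, adjusted p = 0.182 for both with an estimated correlation). Against replicates 3 and 4 it was lower in embryonic markers and interferon genes and higher in the list of core and linker histones (camera adjusted p = 0.00976, 0.00342 and 0.0102, adjusted p = 0.112, 0.112 and 0.2505 with an estimated correlation). All 15 lists called here held with an estimated correlation. With cells of at least 600 UMIs 687 genes passed, with thinned libraries 692, and with counts summed per plate 698.

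The fourth comparison, adult against E12.5 brain, spans both steps and changes gate and sequencing batch. Adult cells were higher in immediate early genes and microglial markers, and lower in ribosomal protein, cell-cycle and respiratory genes. Ecscr was at 969 ± 95.9 CPM in adult brain and 55.2 ± 8.97 CPM at E12.5 (SD, n = 4 each), a log2 fold change of 4.18 (SE 0.24, edgeR adjusted p = 1.15e-17). Pmp22, a myelin-associated membrane protein, was at 559 ± 75.4 and 2.59 ± 3.08 CPM, a log2 fold change of 7.47 (SE 0.47, edgeR adjusted p = 2.01e-16). Every library of one age lay above every library of the other for the genes named here as changed, as the naming rule required of those named for size.

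Of 19 homeostatic markers 16 rose, also adjusted over the list alone (camera adjusted p = 4.03e-28). Selplg was at 10363 ± 123 CPM in adult brain and 801 ± 61.1 CPM at E12.5 (log2 fold change 3.72, SE 0.14). Gpr84 was at 349.7 ± 161 and 269.8 ± 39.9 CPM (edgeR adjusted p = 0.240) and passed with thinned libraries (log2 fold change 0.70). Of 16 immediate early genes 14 rose, also adjusted over the list alone (camera adjusted p = 3.23e-34). Fos was at 1258 ± 75.3 and 6.39 ± 6.79 CPM (log2 fold change 7.37, SE 0.34), Egr1 at 555.0 ± 195 and 7.82 ± 3.89 CPM (6.26, SE 0.34), and Fosb, at 0 in E12.5 brain, was at least 24.8-fold higher. Klf2 was at 106 ± 111 and 126 ± 28.2 CPM (edgeR adjusted p = 0.598) and passed without adult replicate 4 (log2 fold change −1.23). Of 36 ribosomal protein genes 26 fell, and 28 adjusted over the list alone (camera adjusted p = 1.06e-21). The Rpl34 row was at 69.3 ± 14.3 and 1109 ± 536 CPM (log2 fold change −3.96, SE 0.47) and Rpl37 at 36.5 ± 19.7 and 447 ± 180.1 CPM (−3.58, SE 0.37). Rpl30, at 16.1 ± 19.2 and 262 ± 228 CPM (−3.96, SE 1.20), was lost with cells of at least 600 UMIs (−3.54) and with counts per plate (−3.97). Rpl32 was at 792 ± 1402 and 1465 ± 673 CPM (edgeR adjusted p = 0.467), and passed without adult replicate 1 (−4.04).

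Among the largest rises over E12.5, Thrsp and the glutamate transporter Slc1a3, also an astrocyte marker, were at 0 in E12.5 brain and at least 89.4-fold and 67.4-fold higher in adult brain. Lrrc3 was at 397 ± 59.7 and 1.99 ± 2.86 CPM (log2 fold change 7.00, SE 0.51), and Ctsg, a granule protease, at 570.1 ± 591 and 3.47 ± 3.22 CPM (6.98, SE 1.67). All 4 measured granulocyte precursor markers, Prtn3, Mpo, Elane and Ctsg, rose. Gsn, Igf2bp1 and Tpx2 were at 0 in adult libraries, at least 28.0-fold, 16.7-fold and 13.8-fold lower. By summed counts Gpx3 was 138 times lower (exact 95% interval 38.2 to 1144, 2 UMIs in adult), the apolipoprotein Apoc1 121 times (21.6 to 4787, 1 UMI) and the complement factor Cfb 65.2 times (11.6 to 2585, 1 UMI).

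In this comparison edgeR called 1883 of 4883 genes, 870 higher and 1013 lower in adult brain (871 and 1483 without the filter on low counts, 1054 and 943 in DESeq2), and 34.3% of tested genes did not overlap, where chance gives 2.86% for independent libraries and up to 33.3% if those of a plate move together (other splits of whole plates, at most 2.48%). With sequencing batch as a covariate 910 genes passed, and Thrsp (8.38), Slc1a3 (7.95), Lrrc3 (9.50), Ctsg (4.01) and Fosb (5.80) did not, and with thinned libraries 1060 passed.

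The transcripts of the sorted proteins were followed in each comparison. Ptprc, which encodes CD45, was at 189 ± 47.2 CPM in yolk sac, 187 ± 105 in E12.5 brain, 209 ± 69.4 at E18.5 and 60.6 ± 24.3 in adult brain. It fell in the adult against E18.5 (log2 fold change −1.74, SE 0.39) and against E12.5 (−1.63, SE 0.40, lost with sequencing batch as a covariate at −0.91), and did not pass in the other comparisons (edgeR adjusted p = 0.981 and 0.797). Itgam, which encodes CD11b, was at 223 ± 137, 382 ± 173, 849.6 ± 195 and 676 ± 60.6 CPM in the same order. Its rise at E18.5 over E12.5 (log2 fold change 1.13, SE 0.34) was lost with counts per plate (1.20), with the batch covariate (0.19) and without E12.5 brain replicate 3 (1.04) or 4 (0.98). The other comparisons of Itgam did not pass (edgeR adjusted p = 0.231 for yolk sac, 0.607 and 0.0983 for adult against E18.5 and E12.5), except yolk sac with the batch covariate (−1.11) or without yolk sac replicate 3 (−1.16), and adult against E12.5 with thinned libraries (0.91) or these groups alone (0.89).

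Cx3cr1, the reporter's own gene, was at 83.8 ± 46.9 CPM in yolk sac, 162 ± 59.8 in E12.5 brain, 311 ± 80.2 at E18.5 and 325 ± 75.4 in adult brain. It fell in yolk sac against E12.5 brain (log2 fold change −0.93, SE 0.30) and rose at E18.5 (0.90, SE 0.25) and in the adult (0.99, SE 0.29) over E12.5, and adult and E18.5 did not differ past the threshold (edgeR adjusted p = 0.865). All 3 calls of Cx3cr1 were lost with counts per plate (−0.89, 0.95 and 0.98). With the batch covariate the E18.5 value turned to −0.00837 and the adult value was lost at 0.07. The yolk sac call was lost as well with thinned libraries (−0.57), these groups alone (−0.92), DESeq2 (−0.87), and without brain replicate 1 (−0.89) or 2 (−0.70) or yolk sac replicate 1 (−0.66) or 2 (−0.80).

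Over the 3 brain stages, 493 genes were highest at E12.5, 70 at E18.5 and 409 in the adult, each passing edgeR's threshold against both other stages. Lgals1, Gpx3, Gsn and Igf2bp1 were among those highest at E12.5. Crybb1, Ctsl, Ccl2 and the rows of Ccl3 and Ccl4 were among those highest at E18.5, and Tmem119, Selplg and Sall1 among those highest in the adult. With cells of at least 600 UMIs, 249 genes were highest in the adult.

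The share of cells with cell-cycle transcripts, after each cell was thinned to 300 UMIs, was 55.4 ± 5.05% in E12.5 brain (SD, n = 4), 40.5 ± 2.25% in yolk sac (n = 4), 33.7 ± 3.41% at E18.5 (n = 6) and 14.0 ± 6.08% in adult brain (n = 4). Without thinning it was 95.2, 86.0, 77.1 and 35.3%. The difference of yolk sac from E12.5 brain was −14.9 percentage points (two-sided exact permutation test, adjusted p = 0.0286, the smallest that 4 against 4 libraries allow), with every yolk sac library below every brain library. Within the sequencing batch that holds both tissues, yolk sac replicates 1 and 2 were at 43.0 and 41.8% and brain replicates 3 and 4 at 59.9 and 58.6%. The difference lost its call without yolk sac replicate 1 (−15.8), 2 (−15.4), 3 (−14.4) or 4 (−14.3), and kept it without any 1 brain library. Those tests set 3 against 4 libraries and the tissues stayed fully separated, so coarse steps of the permutation p limit these calls. The cell-cycle lists were not called for yolk sac against brain (camera adjusted p = 0.746 for DNA replication and 0.248 for mitosis), and of their members Tubb5 alone fell. The differences were −21.7 for E18.5 against E12.5 and −19.8 for adult against E18.5 (exact permutation, adjusted p = 0.00952 for both), and −41.5 for adult against E12.5 (exact permutation, adjusted p = 0.0286). These tests take libraries as independent. Whole plates allow only 3 or 10 splits per comparison, too few for a p under 0.05.

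**Figure D4:**
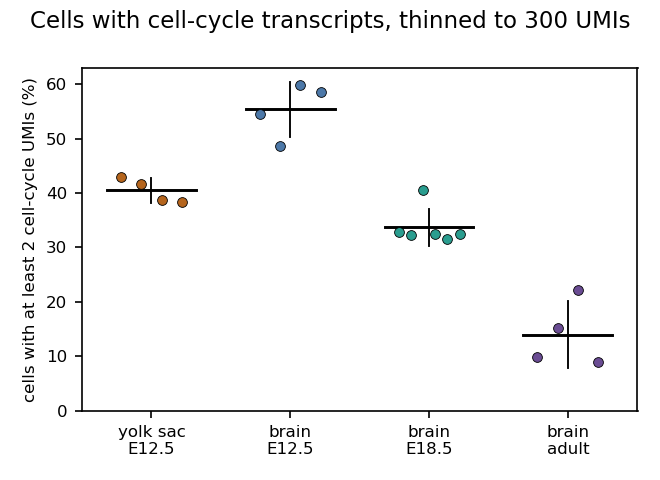
Share of cells with cell-cycle transcripts in each library, in percent on a linear axis, after each cell was thinned to 300 UMIs, for the 4 groups; points are libraries, bars the mean and whiskers 1 SD. The mean was 55.4% in E12.5 brain and 14.0% in adult brain.

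Clustering set apart 134 cells with the lowest level of the complement C1q genes and Csf1r. They made up 78 of 671 yolk sac cells, 54 of 718 E12.5 brain cells, 2 of 992 E18.5 cells and 0 of 631 adult cells, which allows an adult share of up to 0.475%. The share per library was 11.6 ± 1.67% in yolk sac and 7.57 ± 1.94% in E12.5 brain (SD, n = 4 each, exact permutation, adjusted p = 0.0762), and it was lower at E18.5, at 0.197 ± 0.307% (n = 6), than in E12.5 brain (exact permutation, adjusted p = 0.0190). The gate differed between these ages. The clusters were made from these same cells and largely parted them by age, with 621 of 631 adult cells in a single cluster. A low share at a later age may thus come from the clustering, and the permutation tests take libraries as independent. Adult brain did not pass against E18.5 brain (exact permutation, adjusted p = 0.467). Against E12.5 brain the adult libraries, all at 0, lay below every brain library, at 6.42 to 10.5%, and the exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow, became an adjusted p of 0.0571, so this design leaves that difference undecided.

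When each library was held out and its thinned cells were given to the most likely group profile, 93.1 ± 4.28% of yolk sac cells, 91.5 ± 4.50% of E12.5 brain cells, 95.8 ± 1.55% of E18.5 cells and 99.7 ± 0.374% of adult cells went to their own group (SD over libraries). Of the E12.5 brain cells, 40 went to E18.5 brain and 22 to yolk sac, and of the E18.5 cells 38 went to E12.5 brain. In that test the other library of the same plate stayed in the profile. With whole plates held out, the share was 72.3% for E12.5 brain, from 53.5 to 87.8% per library. Then 130 E12.5 brain cells went to E18.5 brain and 72 to yolk sac.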

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

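No test in this part was chosen after its result was seen. In each group of 4 or 6 libraries, a library was listed when its gap to the nearest other library was large against the range of the group by Dixon's criterion, over 169 groups of values; 13 met it, where chance gives 8.4.

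Adult replicate 1 held Rpl32, a ribosomal protein gene, at 2895 CPM where the next adult library held 134 CPM, and Ube2c, a mitotic gene, at 231 against 41.6 CPM. Tgm2 was also highest in this library, at 191 CPM against 93.9 CPM in the next. Adult replicate 3 stood apart in Slc1a3, at 187 against 121 CPM, and low in Pmp22, at 447 against 582 CPM. E18.5 replicate 3 held Mki67, a proliferation marker, at 233 against 122 CPM, and its share of cells with cell-cycle transcripts was 40.6% against 32.8% in the next library. Hemoglobin transcripts summed to 4929 CPM in E18.5 replicate 6 against 436 CPM in the next library, and to 322 CPM in adult replicate 4 against 52.0 CPM. In E12.5 brain, replicate 1 was highest in Gsn, at 261 against 223 CPM, replicate 4 lowest in Lgals1, at 508 against 677 CPM, and replicate 3 held the largest share of cells low in C1q, at 10.5% against 6.90%. In yolk sac, replicate 3 had 309084 UMIs in total against 275579. Apart from the libraries, the 36 empty wells, which the comparisons do not use, held a median of 24 UMIs.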

How the results depend on the processing

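Leaving out the low-C1q cluster and holding out whole plates were chosen after the data were seen; the other alternatives were planned. Of 116 pairs of a named gene and a comparison, 89 kept their direction and side of the threshold under every alternative counted, and 27 did not. That count leaves out the minimum fold change and left-out libraries. Pf4 for E18.5 against E12.5, Rpl32 for adult against E18.5 and against E12.5, and Klf2 for adult against E12.5 changed only with a library left out. Over single alternatives other than left-out libraries, named genes gave 1091 unchanged results, 35 weaker, 5 stronger and 2 reversed, and with 1 library left out 1033 unchanged, 15 weaker and 6 stronger. Lists were tested again only with RLE scaling, with an estimated correlation, without the low-C1q cluster, with 1 library left out and with counts summed per plate. The list results with counts summed per plate are not reported here and are not in the counts below. How they fare with the batch covariate, thinned libraries, other UMI minimums or only the compared groups is not known. The first 3 of these settings gave 132 unchanged and 6 weaker, all 6 with an estimated correlation, and left-out libraries gave 416 and 4. With libraries thinned to the smallest total, 377 genes were called for yolk sac against E12.5 brain, 621 for E18.5 against E12.5, 692 for adult against E18.5 and 1060 for adult against E12.5; fewer genes could be tested there (2353 against 4883). With counts summed per plate the first 3 of these were 493, 660 and 698, with fewer sums than libraries. Sequencing batch as a covariate left 332 genes for E18.5 and 910 for adult against E12.5, and turned Mertk from a log2 fold change of 2.27 to −1.52 and Cx3cr1 from 0.90 to −0.00837 for E18.5. In these fits the batch term rests on the E12.5 libraries alone, and the cause was not tested further. A minimum log2 fold change of 1 left 571 genes for E18.5 against E12.5. With cells of at least 600 UMIs, 687 genes were called for adult against E18.5 and 249 were highest in the adult; the cause was not tested, and the minimum leaves fewer of the shallow adult cells. The yolk sac difference in cell-cycle share ran from −17.2 to −13.5 percentage points with 1 library left out and lost its call without yolk sac replicate 1 (−15.8), 2 (−15.4), 3 (−14.4) or 4 (−14.3). Those tests set 3 against 4 libraries and the tissues stayed fully separated, so coarse steps of the permutation p limit these calls. With whole plates held out, 85.5% of yolk sac and 72.3% of E12.5 brain cells went to their own group; the cause was not tested, and each profile then rests on 1 plate. In DESeq2 the median log2 fold change of all its genes was 0.12 for both E18.5 and adult against E12.5, where edgeR gave −0.03 and −0.07 for 4883 genes. Over those 4883 genes DESeq2 gave 0.000116 and −0.08, so the larger set of genes made most of that difference. The planned restriction to macrophage-like cells was not run, because 3 clusters could not be named. Depth limits the adult libraries most, with 74562 to 99494 UMIs each: in simulated data at these depths, 29% of genes changed 2-fold between adult and E18.5 were recovered. No paired analysis was possible because the labels give no replicate numbers that tie libraries across groups, and the numbers used here only name libraries.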

Other observations

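Among the tests in this part, those of granulocyte precursors and of age for the granule transcripts, of sequencing batch for the interferon and immediate early genes, of 10% or fewer of the cells for the interferon genes, of whole plates for the counts of genes, and of gate or handling were chosen only after the results were seen.

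Further lists moved between E12.5 and adult brain. Of 16 macrophage and microglia transcription factors 13 rose (camera adjusted p = 3.36e-17), of 15 respiratory chain genes 13 fell (camera adjusted p = 1.34e-10), of 16 mitotic genes 14 fell (camera adjusted p = 6.89e-08) and of 13 DNA replication genes 10 fell (camera adjusted p = 0.000337). Adjusted over the list alone these counts were 13, 14, 14 and 10. Of 11 TGF-beta signalling genes 9 rose and the TGF-beta-induced matrix gene Tgfbi fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000337). The innate receptor gene Cd14, Il6ra, Nfkb1 and Nfkbia rose among 9 Toll-like receptor signalling genes, 5 adjusted over the list alone (camera adjusted p = 0.000578), and C1qa, C1qb, C1qc, C5ar1 and Itgb2 rose among 7 complement genes, 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.000875). Aldoa, Gpi1, Ldha, Pgk1 and the Eno1 row fell among 8 glycolysis genes, 5 also adjusted over the list alone (camera adjusted p = 0.000907). Of 16 phagocytic microglia genes 6 fell, and 7 adjusted over the list alone (camera adjusted p = 0.000821, adjusted p = 0.0870 with an estimated correlation). Of 13 MHC class I genes 7 rose and the H2-Q7 row fell, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.0839 with an estimated correlation). Serine synthesis and the long noncoding RNAs were called in no comparison, with the lowest camera adjusted p at 0.248 and 0.151. Malat1, the only long noncoding RNA of that list past the filter on low counts, rose at E18.5 over E12.5 (log2 fold change 1.74, edgeR adjusted p = 0.0157) and did not pass with counts per plate (1.80).

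Some markers of other cell types, picked for naming after their values were seen, moved as well. Gp9 and Cd79b were the only tested markers of platelets and B cells. Of 3 tested neural progenitor or astrocyte markers, 2 fell and 1 rose at E18.5 over E12.5, and 1 fell and 1 rose in the adult over E18.5. Of 4 erythroid markers 1 rose in yolk sac over E12.5 brain. Gp9, a platelet glycoprotein gene, was at 3.26 ± 4.18 CPM in E12.5 brain, 54.6 ± 36.0 at E18.5 and 284 ± 51.0 in adult brain, and rose at each step (log2 fold changes 4.402 and 2.38, edgeR adjusted p = 0.000105 and 0.000249, no overlap of libraries in either). Nes, an intermediate filament gene of neural progenitors, was at 415 ± 56.3, 138 ± 44.1 and 18.7 ± 23.8 CPM and fell at each step (log2 fold changes −1.58 and −2.98, edgeR adjusted p = 6.74e-06 and 2.42e-05, no overlap in either). The B cell receptor component Cd79b fell from 230.1 ± 74.0 CPM at E18.5 to 35.2 ± 22.03 in the adult (log2 fold change −2.73, edgeR adjusted p = 6.00e-07, no overlap). The embryonic globin gene Hbb-y was at 984 ± 782 CPM in yolk sac and 37.5 ± 46.8 in E12.5 brain (log2 fold change 4.96, edgeR adjusted p = 0.00108, libraries overlapping).

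For the count of changed genes, chance can be excluded in all 4 comparisons only if the single libraries are taken as independent. The real grouping was the only one of 35 splits (1 of 35) to reach 774 genes for yolk sac against brain, and the highest other, 176, set yolk sac replicates 1 and 2 with brain replicates 3 and 4, which is sequencing batch 29 against the rest. For E18.5 against E12.5 and adult against E18.5, 1195 and 1050 genes were reached by 1 of 100 splits each, with 274 and 46 as the highest others, and for adult against E12.5, 1883 genes by 1 of 35, with 0 as the highest other. The counts of genes highest at a stage, 493, 70 and 409, were likewise reached by 1 of 100 splits of single libraries each, with 0, 0 and 1 as the highest others. Libraries shared plates, and whole plates allow only 3, 10, 10 and 3 splits in the order of the comparisons, too few for a share under 0.05, with 774, 1195, 1050 and 1883 genes in the real grouping and 176, 123, 160 and 0 as the highest others.

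For the number of lists called, 7 of 35 splits gave at least the 7 lists of yolk sac against brain (highest other 8), 15 of 100 the 11 lists of E18.5 (13), 8 of 100 the 15 lists of adult against E18.5 (16) and 10 of 35 the 13 lists of adult against E12.5 (15). Many of these splits keep part of the real contrast, so their number is no clean measure of chance. Splits that kept 3 of the 4 libraries of a group together called 4 to 8 lists for yolk sac against brain and 9 to 15 for adult against E12.5, and those that parted both groups evenly called 0 to 2 in either. With the groups of 4 and 6 libraries, splits were ordered by how many of the smaller group's libraries fell in the group of 4. With 3 there, the splits called 9 to 12 lists for E18.5 against E12.5 and 11 to 16 for adult against E18.5. With 2 there they called 0 to 7 and 0 to 5, and with 1 there 2 to 11 and 1 to 11. With 0 there, all 4 stood together in the group of 6, which keeps part of the real contrast, and 10 to 13 and 13 to 16 lists were called. Whether chance accounts for the number of lists stays open.

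Transcripts of granule proteins appeared in microglia libraries in a different mixture from library to library. Prtn3 stood at 543 and 6406 CPM in the adult replicates 1 and 2 of a plate, a ratio of 11.8 (exact 95% interval 8.92 to 15.9), while Mpo was at 1839 and 1253 CPM and Ctsg at 161 and 835 CPM there, so age cannot be the whole cause. A few granulocyte precursors in the sort, which the gate would admit only at intermediate CD45 and CD11b, are argued against, since the richest 5% of adult wells held 17.9% of the 1889 UMIs of Prtn3, Mpo, Elane, Ctsg and Ly6c2, and spread in proportion to depth gives 16.1 to 19.4%. An equal spread of stray molecules over all wells is argued against by the 8 empty adult wells, which held 0 of these UMIs (exact upper limit 3.69) where 23.5 would be met, although spread in proportion to depth would give 1.07. Molecules that entered a library's pool before amplification may be a source, which was not tested, and a part set by age stays open.

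Interferon response genes were higher in yolk sac and differed between its plates. Sequencing batch is argued against as the whole cause of the higher level in yolk sac. The highest brain library of the batch of yolk sac replicates 3 and 4 held 0.167 of the summed level of the lower of these (947 against 5662 CPM). A tissue difference is met by the plate of replicates 1 and 2, which shares no batch with those and in which 9 of 9 genes were called higher than in the E12.5 brain plates. As the whole source, 10% or fewer of the cells are argued against only if molecules did not spread between wells, which was not tested for these genes. A UMI of them was held by 68.4% of thinned cells of replicates 3 and 4 (exact 95% interval 63.1 to 73.4%, cells taken as independent). The share was 52.0% in replicates 1 and 2 and 22.6% in E12.5 brain. Whether a small group holds a larger part stays undecided. The richest 10% of cells of replicates 3 and 4 held 33.7% of their UMIs, where chance gives 25.3% and at most 27.6%. The cause of the difference between yolk sac plates was not tested. It could be sequencing batch, which also parts these plates, a preparation, or an animal if the subject number that the plates share covers several animals.

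Immediate early genes were low in all E12.5 libraries and high at E18.5 and in the adult. Sequencing batch is argued against, as the higher of yolk sac replicates 3 and 4, which share the batch of all later libraries, held 0.191 of the lowest later library (1042 against 5463 CPM). Depth is argued against, as 100% of the called members that could still be tested were called again with libraries thinned to 1 total. Between E18.5 and adult, where the gate is the same, the list rose again (camera adjusted p = 6.05e-06), from 5994 to 11436 CPM in sum, with a median log2 fold change of 0.45, under the 0.5 that an effect of gate or handling was taken to allow, and a mean of 0.64. A change of gate does not account for this later rise, but whether handling does is not known. For the larger rise from E12.5 to E18.5 gate or handling cannot be told apart from age.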
